A study of Homo sapiens with 4 samples.

How the data were processed

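RNA immunoprecipitation followed by sequencing (RIP-seq) recovers the RNA bound to a protein with an antibody against that protein, and compares it with the input RNA that was not precipitated. Here the antibody was against YTHDF3, a cytoplasmic reader of N6-methyladenosine (m6A), per the labels' protocols. The study held 4 libraries, 1 immunoprecipitate (IP) and 1 input from SiHa cells, an established human cervical squamous carcinoma line, and 1 IP and 1 input from a YTHDF3 knockout of SiHa. Libraries were made with a stranded mRNA kit, per the labels' protocols. There was 1 library per group, so no value has a replicate error and no test across replicates was possible. No precipitation with a non-specific antibody was analysed here.

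Per the submitters' processing notes, FastQC 0.11.7 was used and the genome builds GRCh38 and hg38 were named. The aligner, the counting tool, the use of strand and the statistical test are not given in the sources used here. For each cell line the authors deposited a table of genes with Ensembl identifiers, symbols and biotypes. Per the file headers, each row held a log2 fold change, a p-value, an adjusted p-value (FDR), and a level of the gene in 2 libraries. The headers named 1 of these as the input, and the other was taken as the IP of that cell line because its name lacks that word. The lane given in its name differs from, or is lacking in, the sample's title, and this doubt applies to all IP levels. The deposited log2 fold change is that of this column over the input column, up to a constant, and is called the log2 fold enrichment of IP over input for that reason. The deposited levels were treated as a signal of unknown unit, because they were not whole numbers and shared no common step per library. Total reads and depth per library are unknown for this reason, and no counting interval is given. The deposited tables were already thresholded. All rows were called up, the lowest log2 fold enrichment was 1.00 in both tables, and the highest p-value was 0.0500 in SiHa and 0.0498 in the knockout. The adjusted p-value was not used as a threshold by the authors: it reached 0.164 in SiHa and 0.208 in the knockout.

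How the deposited log2 fold enrichments and p-values were made was worked out from the values. In every row the log2 fold enrichment equalled log2 of IP level over input level plus a constant, 1.01 in SiHa and 0.81 in the knockout. A 2-fold enrichment in the deposited tables therefore stood for an IP to input level ratio of 0.996 in SiHa and 1.14 in the knockout. The p-values were met by a random sampling model of the MA plot in which levels are taken as read counts. Over 3641 SiHa and 2332 knockout genes the largest deviation was 0.0021 and 0.0020 in log10 p, the size that rounding of small p-values to 3 digits can give. The p-values therefore measure a sampling spread that the levels would have as counts, and not a spread between cultures. In that model the totals of the level columns over all genes tested were 242828 for IP and 487830 for input in SiHa, and 345887 and 607818 in the knockout. The fit took the constant as log2 of the input total over the IP total. In the model, leaving out the constant therefore only undoes a scaling to the totals. The number of genes tested followed from the ratio of adjusted p to p, which makes every rank whole: 13529 in SiHa and 11034 in the knockout, with mean deviations from whole ranks of 0.00027 and 0.00019, against 0.175 and 0.152 at the next best numbers.

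Genes were joined by Ensembl identifier. Identifiers and symbols were unique within each table (0 duplicates). Locations came from the RefSeq annotation of GRCh38.p14, matched by symbol or older symbol for 3844 of 3905 listed genes. A total of 26 gene lists, the rule for named genes, the comparisons and most alternatives were fixed before the data were examined. For each list the number of members listed in each table was counted. The share of its SiHa-listed members missing from the knockout table and its median log2 fold enrichment were placed among 10000 random lists of the same size, drawn from the listed genes and matched on level in 5 bins, where the level is the higher of IP and input. Lists with under 5 listed members were not placed. These percentiles describe 4 libraries and are not p-values. The counts of lists said to be given by chance treat members as unrelated genes. Members of a list can be related, so more lists may lie outside without any effect of YTHDF3. The named genes were YTHDF3 and its paralogs. To these were added the 10 largest folds in each table, the 10 largest listed in that table alone, and the 10 highest and 10 lowest ratios of SiHa to knockout fold among shared genes, all at or above the table's median level. From each gene list, up to 4 members with the largest SiHa fold and any member listed in 1 table only were added. Some genes that the rule names are not reported here. Genes outside this rule are said to be chosen after their values were seen.

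Alternatives were a 4-fold threshold, an adjusted p of at most 0.001 or 0.05, a minimum IP level of 1, joining by symbol, protein-coding genes only, equal list lengths, levels with pseudocounts of 0.1 and 1 without the constant, centring, and random lists with other matching. The sources do not name the sampling model, and the totals are estimates from it. The 2 tables were normalised separately, so a fold set across them rests on each table's constant. Some of the computations were tested on simulated data. The simulated p-values were made by the same sampling model that was then fitted, so this does not test the model itself. The number of genes tested was recovered with an error of 0 in both simulated tables, and the input total within 0.12% for SiHa and 0.69% for the knockout. Of 100 simulated SiHa lists of 15 genes, 7 lay outside the central 95% without a shift, 60 with a log2 shift of 0.5 and 100 with a log2 shift of 1. This simulation used the median SiHa fold and fewer random lists. The share missing from the knockout table was not simulated. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.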

Results

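RNA recovered with a YTHDF3 antibody was profiled by RIP-seq in SiHa cells and in SiHa cells labelled as YTHDF3 knockout. Each had 1 IP and 1 input library. The design poses 2 questions. It asks which transcripts the YTHDF3 antibody enriched over input in SiHa, and which of these were enriched in cells labelled as YTHDF3 knockout. The authors' deposited tables listed 3648 enriched genes in SiHa, 27.0% of 13529 genes tested, and 2340 in the knockout, 21.2% of 11034 genes tested. The median IP level of listed genes was 21.2 in SiHa and 23.8 in the knockout, and the median input level was 10.7 and 8.08, in the unit of the deposited tables. Sequencing depth is unknown. With 1 library per group, the differences below have no replicate check.

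The gene targeted by the knockout was checked before the others. YTHDF3 (ENSG00000185728, GRCh38 chromosome 8, 63168553 to 63212788) was listed in the authors' deposited table for SiHa with a 4.41-fold enrichment of its own transcript, at an IP level of 25.8 and an input level of 11.7. It was not listed in the knockout. The same held for its paralogs: YTHDF1 (ENSG00000149658) was enriched 3.23-fold and YTHDF2 (ENSG00000198492) 2.62-fold in the authors' deposited table for SiHa, and neither was listed in the knockout. A gene that is missing from a table either did not pass its thresholds or was not tested there. Its level in that cell line is not known, so the absence of YTHDF3 from the knockout table does not measure how much of its transcript was left.

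The leading genes in SiHa are given among those at or above the table's median level. The highest of all folds in the authors' deposited table was that of USB1, a phosphodiesterase that trims U6 snRNA (ENSG00000103005, chromosome 16, 57999603 to 58021618), at 25.7-fold. Its input level was 6.88 and its IP level 88.0. Deposited folds include the constant and so exceed the ratio of the levels. HSP90B1, the HSP90 chaperone of the endoplasmic reticulum (chromosome 12, 103930410 to 103947926), was enriched 15.8-fold and had the highest IP level among the 10 leading genes, 2310. LEO1, a subunit of the PAF1 elongation complex, stood at a log2 fold of 3.99, HTATSF1, a splicing and elongation factor, at 3.93, the hyaluronan receptor HMMR at 3.89 and the splicing factor SLU7 at 3.82 in the same authors' deposited table. The homeobox gene SIX2 had a log2 fold of 4.18 in the authors' deposited table. The other 3 of these 10 leading genes were MIR1244-2, HSP90AA2P and NPM1P27, at log2 folds of 4.44, 4.14 and 3.82 in the authors' deposited table. The last 2 are processed copies of HSP90AA1 and NPM1, and reads may be split between such near-identical copies, so their values are uncertain. MIR1244-2 spans only 85 bases, and the transcript its reads came from is not known, so its value is uncertain too. Below the median level, some genes had larger folds than most of these, among them ZNF441 at 4.54 and ZNF823 at 4.21 in the authors' deposited table. Over all listed genes the median was 4.12-fold, and 52.5% of them were enriched at least 4-fold. Protein-coding genes made up 96.8% of the list and pseudogenes 2.14%. The listed genes held 69.3% of the summed IP level of all genes tested and 15.2% of the summed input level. By the authors' adjusted p-value, 698 of the 3648 genes were above 0.05.

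Among the fixed gene lists in SiHa, zinc finger genes of the ZNF series, many of which encode KRAB repressors, had the most listed members, 120, and a median log2 fold of 2.35 against 1.97 for random lists of the same level (percentile 100 of 10000 random lists). ZNF441, ZNF823, ZNF721 and ZNF669 led this list. Chromatin regulators had 31 of 34 members listed, with a median log2 fold of 2.55 against 2.25 for random lists (percentile 96.5). In this list BPTF, SMARCA2, EZH2, the methyltransferase of Polycomb complex 2, and NSD1 led. Cell cycle genes had 24 of 47 members listed at a median of 2.02, led by the proliferation marker MKI67 and by BUB1B, TOP2A and CCNB1. Of these, MKI67 reached an IP level of 986. At the low end stood WNT signalling (13 of 30 listed, median 1.45, percentile 0.09), cholesterol and fatty acid synthesis (9 of 30, median 1.58, percentile 1.36), glycolysis (8 of 28, median 1.63, percentile 1.73), histone genes (16 listed, median 1.69, percentile 0.33) and cytosolic ribosomal proteins (21 listed, median 1.77, percentile 0.90). Such low percentiles mean weaker enrichment than other listed genes of the same level, not depletion. In all but 3 listed SiHa genes, and in all listed knockout genes, that level was the IP level, the numerator of the fold. Matching on it does not control for expression, since at an equal IP level a lower fold is a higher input level. Without matching on level only WNT signalling stayed outside the central 95% among these 5 (percentile 0.20), and the others were at 2.51 (histone genes) to 5.09 (ribosomal proteins), while the chromatin regulators were at 99.9. In all, 6 of the 21 lists that could be placed lay outside the central 95% of random lists, where chance gives about 1.05. The mitochondrially encoded genes had 0 listed members in either cell line, and the markers of other cell types 1, the neuronal MAP2, which was listed in both.

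In the knockout 4 of the 10 leading genes were among the 10 that led in SiHa, with the same limit on level, and all 10 were listed there. In the authors' deposited table for the knockout, USB1 was again highest at 45.4-fold with the constant included, at an input level of 8.03 and an IP level of 207. HMMR followed at a log2 fold of 5.14, and LARP7, a protein of the 7SK complex, at 5.11. RNU1-106P, a U1 snRNA pseudogene whose reads may come from other U1 copies, stood at 5.07 and NKAP at 5.07 in the authors' deposited table. There HTATSF1 stood at 4.92, HSP90B1 at 4.91 or 30.1-fold, CCDC34 at 4.88, the histone chaperone ANP32B at 4.84 and nucleolin (NCL) at 4.82. The 4 that led in both were USB1, HSP90B1, HTATSF1 and HMMR. The median enrichment in the knockout was 5.38-fold, 66.6% of the genes were enriched at least 4-fold, and 191 genes were enriched at least 16-fold against 10 in SiHa. The m6A writer genes ZC3H13, VIRMA, METTL14 and WTAP were listed in both cell lines. Of the writers and erasers 5 were listed in the knockout, at a median log2 fold of 3.54 against 2.51 for random lists (percentile 96.4). The translation factors had 15 of 35 members listed, at a median of 2.55, and the ribosomal proteins 19, at 2.17 (percentile 1.11, and 19.6 without matching on level). The zinc finger genes had 47 listed, at 2.54 (percentile 98.9, and 73.4 without matching). These last 2 were the only ones outside the central 95% of the 12 lists that could be placed in the knockout, where chance gives about 0.6. The listed genes held 38.3% of the summed IP level and 6.14% of the summed input level. By the authors' adjusted p-value, 459 of the 2340 genes were above 0.05.

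Most genes listed as enriched in the knockout were also listed in SiHa. Of the 2340 genes listed in the knockout, 2083 (89.0%) were listed in SiHa, and these made up 57.1% of the SiHa list. If the same genes had been tested in both cell lines, independent lists of these lengths would share 774 genes among 11034 tested or 631 among 13529, so the observed overlap was 2.69 to 3.30 times larger. All 4 listed HSP90 genes were shared (HSP90AA1, HSP90AB1, HSP90B1 and the pseudogene HSP90AA2P; this family was chosen after its values were seen), as were 27 of the 31 chromatin regulators listed in SiHa, 18 of 21 ribosomal proteins and 15 of 20 translation factors. MYC, the proto-oncogene, was enriched 8.28-fold in SiHa and 5.62-fold in the knockout in the authors' deposited tables, and MKI67 was shared as well. Across the 2083 shared genes the log2 fold enrichments correlated with a Pearson r of 0.73 and a Spearman rho of 0.72. This is a correlation across genes, which are not independent replicates. Within 5 bins of level the rho ranged from 0.53 to 0.83.

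**Figure D1:**
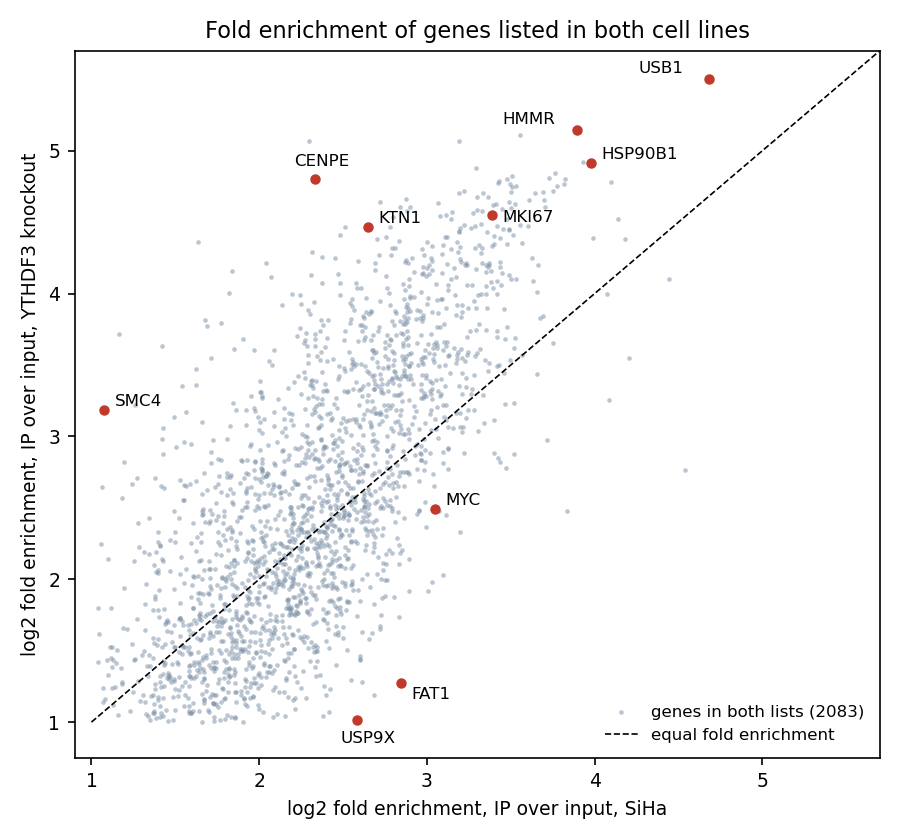
Log2 fold enrichment of IP over input in SiHa (horizontal) against the YTHDF3 knockout (vertical), as deposited, for the 2083 genes listed in both; each point is a gene, red points are named genes and the dashed line marks equal enrichment. The points spread more along the vertical axis (SD 0.95) than along the horizontal axis (SD 0.59), and 60.1% lie above the line.

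Among shared genes, fold enrichment differed between the cell lines in both directions. It was higher in the knockout for 1252 genes and higher in SiHa for 831, with a median log2 ratio of SiHa to knockout of -0.18 and quartiles of -0.70 and 0.23. The sign of this median depends on how the 2 tables are scaled: centring each on its own median, which shifts every ratio alike, gave 0.21. The counts of genes above and below 0 depend on the scaling in the same way, and no overall direction is given. At least 2-fold higher values were seen in the knockout for 284 genes and in SiHa for 35. Among the 987 shared genes at or above the median level in both tables, the lowest log2 ratios of SiHa to knockout fold, taken from the authors' deposited tables, belonged to RNU1-106P (-2.77), the mitotic kinesin CENPE (-2.47), AKAP9 (-2.14), the condensin subunit SMC4 (-2.11) and the meiotic axis protein gene SYCP2 (-1.96), followed by GOLGB1, DEK, PAXBP1, ANP32E and KTN1 with ratios from -1.88 to -1.81. For SMC4 the input level was 68.3 in SiHa and 8.14 in the knockout, whereas its IP level was 71.6 and 42.0. CENPE, SYCP2 and PAXBP1 likewise had lower input and IP levels in the knockout. For CENPE the input level was 21.6 in SiHa and 2.34 in the knockout, and the IP level 54.1 and 37.2. RNU1-106P, AKAP9, GOLGB1, DEK and ANP32E had higher IP levels in the knockout. The 13 shared cell cycle genes also had lower input levels in the knockout, at a median log2 ratio of knockout to SiHa of -2.68 against -0.52 for all shared genes, in separately normalised tables. For KTN1, which encodes kinectin, the IP level was 156 in SiHa and 839 in the knockout at input levels of 49.9 and 66.8. Among the same 987 genes, the highest log2 ratios of the authors' deposited tables belonged to the deubiquitinase gene USP9X (1.57), the protocadherin gene FAT1 (1.57) and PAFAH1B1 (1.35), followed by TMEM30A, PSMD10, GORASP2, ANO6, NEO1, ADNP and QRICH1 with ratios from 1.34 to 1.14. All 20 are set across separately normalised tables, and each rests on 4 single libraries.

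A total of 1565 genes, 42.9% of the SiHa list, were listed in SiHa and not in the knockout. They had a median log2 fold of 1.72 and a median IP level of 14.4 in SiHa, against 2.32 and 30.4 for the shared genes. Among those at or above the median level of the SiHa table, the largest folds in the authors' deposited table belonged to MNS1, a gene of cilia and sperm flagella (3.78), the pseudogene PTMAP4 (3.65), the kinase-anchoring protein gene AKAP12 (3.49), the centriole duplication factor CEP152 (3.34) and the myosin gene MYO5C (3.19). PLEKHA5, LINC00106, CKAP2L, MEGF9 and NFIA followed in the authors' deposited table, at 3.12 to 2.69. As for the pseudogenes named above, reads of PTMAP4 may come from near-identical copies. The share of SiHa genes that were also listed in the knockout increased with SiHa fold, from 25.7% in the lowest quartile to 87.4% in the highest, and with SiHa level from 31.8% to 81.6%. Of the 390 genes in the top quartile of both, 387 (99.2%) were listed in the knockout. The 3 others were MYO5C, CKAP2L and LINC00106.

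**Figure D2:**
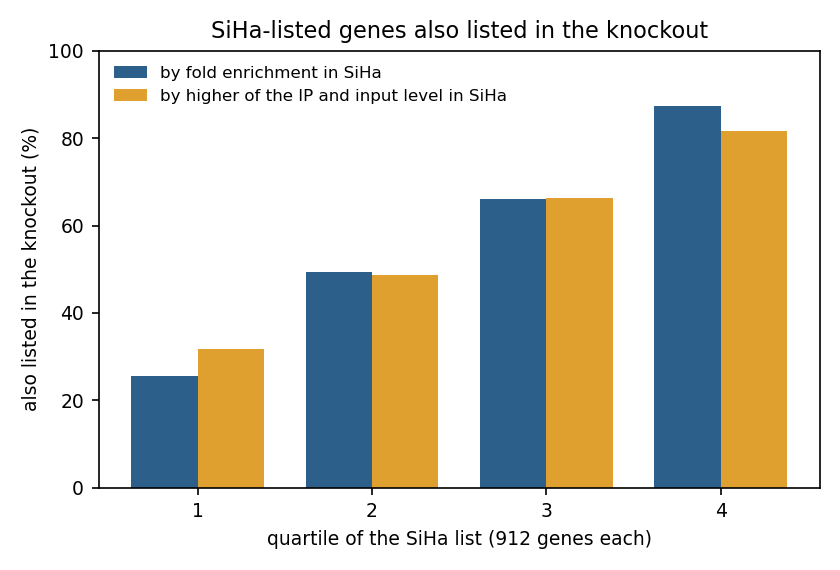
Percentage of SiHa-listed genes that were also listed in the YTHDF3 knockout (vertical), by quartile of SiHa fold enrichment (blue) or of SiHa level (yellow). The percentage goes from 25.7% to 87.4% with fold and from 31.8% to 81.6% with level.

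Members of 6 fixed lists were missing from the knockout table more often than SiHa-listed genes of the same level drawn at random. Of 10 epithelial and mesenchymal genes listed in SiHa, 9 were not listed in the knockout, against a median of 40.0% for random lists (percentile 99.97). These included E-cadherin (CDH1), enriched 4.24-fold in the authors' deposited table for SiHa, and EPCAM, SMAD3, TGFBR1 and TGFBR2, whereas TGFB2 was listed in both and ITGB1 and ZEB1 in the knockout only. Of 15 growth factor, PI3K and mTOR genes 12 were missing (80.0%, percentile 99.7), among them the receptor genes EGFR (3.63-fold in the authors' deposited table for SiHa), MET (4.62-fold), IGF1R and INSR. MTOR and TSC1 were listed in both. Of 9 cholesterol and fatty acid synthesis genes 7 were missing (77.8%, percentile 99.98), including ACLY at 3.56-fold in the authors' deposited table for SiHa and the fatty acid desaturase gene SCD. In WNT signalling 10 of 13 were missing (76.9%, percentile 99.3), among them CTNNB1, which encodes beta-catenin, and GSK3B, LRP5 and LRP6. In glycolysis 6 of 8 were missing (percentile 99.0), among them HK1 and PDK3, whereas PKM was listed in both. In the squamous keratinocyte markers 4 of 6 were missing (66.7%, percentile 98.6), among them KRT8, KRT18 and SFN. Of the missing genes named so far, EPCAM, TGFBR2, IGF1R and LRP6 were above 0.05 by the authors' adjusted p-value in SiHa itself. With random lists also matched on SiHa fold, WNT signalling, glycolysis and the keratinocyte markers were no longer outside the central 95%, and 4 other lists were: zinc finger genes (percentile 100), stress granule and P-body genes (98.5), Hippo and YAP genes (98.2) and, with a low share, ribosomal proteins (0.26). With matching on level, 6 of 21 lists lay outside it, where chance gives about 1.05.

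**Figure D3:**
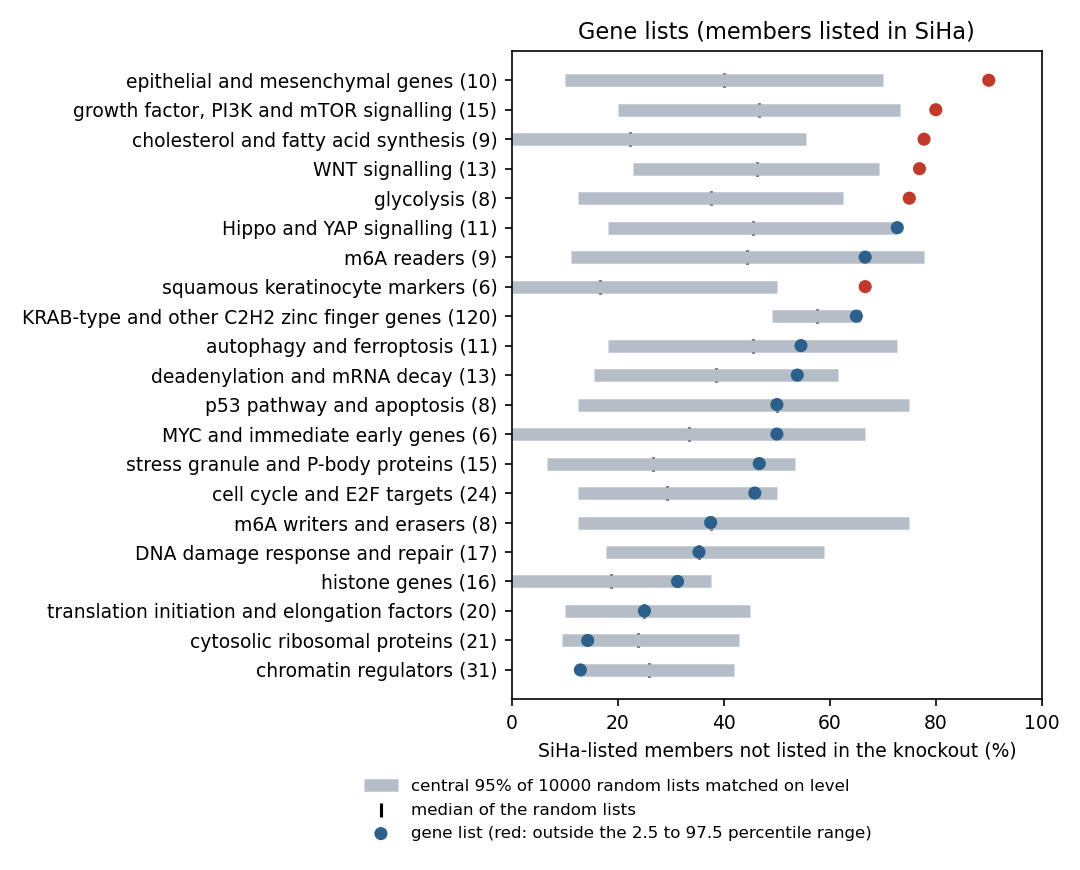
Percentage of the SiHa-listed members of each gene list that were not listed in the knockout (points; the number of members in parentheses), with the central 95% (grey bars) and the median (black ticks) of 10000 random lists of SiHa-listed genes matched on level. The 6 red points lie outside the central 95%, and the lowest of them is that of the keratinocyte markers (66.7%).

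With matching on level, the remaining lists lay inside the central 95% for this share. Of 9 m6A readers 6 were missing from the knockout table (66.7%, percentile 93.2), namely YTHDF1, YTHDF2, YTHDF3, IGF2BP2, FXR2 and ELAVL1, and FXR1 and HNRNPC were listed in the knockout only. Of 13 genes of deadenylation and mRNA decay 7 were missing (percentile 91.5), including CNOT6, CNOT6L, PAN3 and UPF1. Of 15 stress granule and P-body genes 7 were missing (percentile 93.4), including AGO2, TNRC6B and PABPC1. Of 11 Hippo and YAP genes 8 were missing (72.7%, percentile 97.0), including LATS1, LATS2, WWTR1 and TEAD1. Of the 120 zinc finger genes 78 were missing (65.0%, percentile 96.6), against a median of 57.5% for random lists matched on level. That median was 46.7% with matching on level and fold and 42.5% without matching, and the percentile was 100 with either. The cell cycle list had 11 of 24 missing (45.8%, percentile 95.2), among them CCNA2, CCNE1 and PLK1. The chromatin regulators stood at the other end, with 4 of 31 missing (12.9%, percentile 2.70): CHD7, KMT2D, SETD1B and TET2. Their percentile was 0.02 without matching and 44.5 with matching on level and fold. The DNA damage list (6 of 17 missing, percentile 48.1), the writers and erasers (3 of 8, percentile 41.9) and the translation factors (5 of 20, percentile 51.9) were close to the middle of the random lists. The histone genes (5 of 16, percentile 87.9), ribosomal proteins (3 of 21, percentile 12.1), p53 and apoptosis genes (4 of 8, percentile 59.8), MYC and immediate early genes (3 of 6, percentile 71.8) and autophagy and ferroptosis genes (6 of 11, percentile 73.5) were also inside the central 95%. Of the lists too short to be placed, 3 of 4 interferon and innate immune genes, 1 of 4 hypoxia and angiogenesis genes and 0 of 1 structured non-coding RNA were missing. Among the missing genes named here, FXR2, ELAVL1, PAN3, LATS2, WWTR1, CHD7 and TET2 were above 0.05 by the authors' adjusted p-value in SiHa. Some of the missing zinc finger genes were too, among them ZNF41, ZNF182, ZNF484 and ZNF551, and others were not. FXR1, listed in the knockout only, was above 0.05 there.

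A total of 257 genes, 11.0% of the knockout list, were listed in the knockout and not in SiHa, at a median log2 fold of 2.02. The SiHa list was longer, which by itself leaves more genes specific to SiHa. Of these genes, 134 were enriched at least 4-fold in the knockout. Among those at or above the median level, the largest folds in the authors' deposited table for the knockout belonged to NEXN, an actin-binding protein gene (4.75), PRG4, which encodes lubricin (4.24), ANKRD26 (3.96), the splicing factor LUC7L3 (3.89) and the non-coding AL161431.1 (3.50). They were followed in the authors' deposited table by the long non-coding RNA PVT1 (3.41), LRRFIP2 (3.01), the long non-coding RNA ESRG (3.01), BFSP1 and PPIL4 (2.51). The span of PVT1 (chromosome 8, 127794524 to 128101256) holds that of RNU1-106P (127999131 to 127999294), so their values may not be separate. PRG4 and AL161431.1 had high knockout IP levels of 321 and 396. The small nuclear and nucleolar RNAs SCARNA5, SCARNA21 and SNORD62B and the double-strand break repair genes NBN and RAD50 were also listed in the knockout only. Of these, SCARNA5 was above 0.05 by the authors' adjusted p-value in the knockout.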

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

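No paired analysis was possible because each group had 1 library, and for the same reason no replicate could be left out. The unit of the levels, and with it the depth, is unknown, which limits what low levels can show. The 5 gene counts (SiHa list, knockout list, shared, SiHa only, knockout only) stayed within 1.5 times of the reported values for protein-coding genes only and for an adjusted p of at most 0.05. A minimum IP level of 1, joining by symbol and the choice of row per gene changed nothing, because no gene was removed or repeated. With both lists held to 4-fold or more, 1917 SiHa, 1559 knockout, 1207 shared, 710 SiHa-only and 352 knockout-only genes were left, so a smaller part of the knockout list was shared. At an adjusted p of at most 0.001 these counts were 1787, 1308, 1076, 711 and 232. With equal list lengths, 668 genes were specific to each cell line, the same number in both by construction. Tests chosen after the data were seen were the adjusted p of 0.05, matching on SiHa fold, the shared count at equal lengths, a level ratio of at least 2 without the constant and a 4-fold threshold against the whole other list. The level ratio left 1907 SiHa, 1292 shared, 615 SiHa-only and 435 knockout-only genes. The last left 457 SiHa-only and 134 knockout-only genes. The median log2 ratio of SiHa to knockout fold over shared genes moved from -0.18 to -0.37 and -0.32 from levels with pseudocounts of 0.1 and 1 without the constant, and reversed to 0.21 after centring, which adds the difference between the tables' medians by construction. The number of gene lists with an outlying share was 6 or 7 under every matching run, but not with the same lists. The epithelial and mesenchymal, growth factor and cholesterol lists were outside in all. With matching on fold 3 lists left and 4 entered, and without matching glycolysis and the keratinocyte markers left (percentiles 96.1 and 85.9) and zinc finger, chromatin and ribosomal genes entered (100, 0.02 and 0.33). Without matching on level, the lists with an outlying median fold went from 6 to 3 in SiHa and from 2 to 1 in the knockout (the cause was not tested). In the knockout both lists left, and the chromatin regulators entered (percentile 99.8, and 96.2 with matching on level). Of the named genes' folds, 182 with a pseudocount of 0.1 and 198 with 1 fell below 2-fold without the constant, and 265 and 249 did not.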

Other observations

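Of the tests here, only that of the tables' constants was chosen before its result, or values closely tied to it, had been seen; the 12 gene families and the comparison of input levels were chosen after. Input levels of shared cell cycle and histone genes were lower in the knockout table. Over the 2083 shared genes the median log2 ratio of knockout to SiHa input level was -0.52, in separately normalised tables, so lists are set against random lists of shared genes matched on level. All 13 shared cell cycle genes were lower in the knockout, at a median of -2.68 (random lists -0.51), as were all 11 histone genes at -3.02 and all 27 chromatin regulators at -1.36, each at percentile 0. The input level of MKI67 was 189 in SiHa and 11.2 in the knockout, that of TOP2A 138 and 17.0, and that of BUB1B 22.7 and 2.56. Of the 11 fixed lists with enough shared members 3 were outside the central 95%, and the translation factors (-0.20, percentile 88.3) and ribosomal proteins (-0.62, percentile 31.4) were inside. No chance count is given, because this comparison was chosen after values were seen. With 1 input library each, these values compare 2 libraries and not the effect of the knockout.

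Kinesins, the microtubule motors, were among the most enriched families in both cell lines. They were counted by KIF symbols, which leaves out CENPE. In SiHa 22 were listed at a median log2 fold of 2.55 (percentile 98.6 of level-matched random lists). In the knockout 20 were listed at 3.11 (percentile 99.2), and all 20 were shared. KIF5B, KIF18A, KIF4A and KIF15 had log2 folds of 3.57, 3.42, 3.40 and 3.38 in the authors' deposited table for SiHa and 4.35, 3.70, 4.04 and 4.08 in that for the knockout. Coiled-coil domain (CCDC) genes stood at 2.31 in SiHa (24 listed, percentile 97.4) and 3.43 in the knockout (26 listed, percentile 100), and centrosomal (CEP) genes at 3.16 in the knockout (18 listed, percentile 99.95) against 2.06 in SiHa (25 listed, percentile 61.9). All 15 shared CEP genes had a lower input level in the knockout, at a median log2 ratio of -1.18 (percentile 0.58). Of the 20 shared kinesins 17 had a lower one, at a median of -0.89 (percentile 3.08). For the shared CCDC genes the median was -0.34 (percentile 83.4). The 4 HSP90 genes had a median log2 fold of 3.88 in SiHa and 4.63 in the knockout.

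Families at the low end were the solute carriers, with 20 listed in SiHa at 1.55 (percentile 0.05) and 13 of the 20 missing from the knockout table (65.0%, percentile 99.5), and the proteasome subunits, with 14 listed in the knockout at 1.57 (percentile 0.11). The TMEM genes had 10 of 16 missing (percentile 96.8). SR splicing factors (7 in the knockout, median 1.58, percentile 2.71), mitochondrial ribosomal proteins (8, median 1.99, percentile 16.8), nucleoporins (7, median 1.81, percentile 12.9), ubiquitin-specific proteases (20, median 2.28, percentile 45.8) and DEAD and DEAH box helicases (24, median 2.74, percentile 76.0) were inside the central 95% there. Few CCDC genes (4 of 24, percentile 0.045) and kinesins (2 of 22, percentile 0.35) were missing. With the solute carriers these were 3 of 10 placed families outside the central 95%, with no chance count given because the families were chosen after values were seen. Genomic span was weakly related to fold, with a Spearman rho across genes of 0.14 in SiHa and 0.057 in the knockout.

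The main pattern is that 2083 of the 2340 genes enriched by a YTHDF3 antibody in cells labelled as YTHDF3 knockout were also enriched in SiHa, 2.69 times the overlap of independent lists among 11034 genes. Abundance alone, through thresholds that favour high levels, was taken to leave the folds of shared genes unrelated at a given level. The median rho within level bins was 0.67 (95% bootstrap interval over genes 0.62 to 0.72). That test cannot decide, since the level is nearly always the IP level. Input levels alike in both cell lines would relate the folds too. Less YTHDF3 in otherwise equal precipitations would narrow the folds, but their SD over shared genes was 1.62 times larger in the knockout (1.57 to 1.66 over genes). This does not decide it, since shared genes had passed in the knockout and the spread between precipitations is not known. Recovery of certain transcripts by the antibody or the beads without YTHDF3, another protein bound by the antibody, and a bias tied to transcript sequence stay open, as does a mislabelled library.

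The second pattern is the 1565 SiHa genes missing from the knockout table. The constant and column totals of the knockout table together would remove 488 SiHa genes if their levels had been equal, so this scaling accounts for part of the pattern at most. Weak enrichment near the threshold stays open: the share listed in the knockout was 61.7 percentage points higher in the top than in the bottom quartile of SiHa fold (58.1 to 65.4, 2 standard errors over genes either way), but a uniform loss of recovery would give such a gradient too. Of the genes in the top quartile of SiHa fold and of level, 3 were missing (MYO5C, CKAP2L and LINC00106). That level is nearly always the IP level, so these need not be abundant transcripts. Their SiHa input levels were 10.1, 10.9 and 14.7, against a median of 10.7 for the SiHa list. This count does not decide on a loss of recovery by YTHDF3, since a partial loss would leave strongly enriched genes above 2-fold. Loss of recovery cannot be told apart from low expression or not being tested in the knockout, since levels of unlisted genes are not known.

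The third pattern is the larger share of genes missing from the knockout table in 6 fixed lists. A lower SiHa fold of these genes stays possible for the keratinocyte markers, whose percentile went to 83.2 with random lists matched on level and fold, glycolysis (92.7) and WNT signalling (90.5). It does not explain the epithelial and mesenchymal genes (99.9) or the growth factor, PI3K and mTOR genes (99.3), whereas for cholesterol and fatty acid synthesis (98.1) it stays open, since the list's fold was still at percentile 0.36 of the matched lists. A candidate explanation for these lists is lower expression in the knockout cells and another is recovery that depends on YTHDF3. These were not separated, since the knockout levels of missing genes are not known.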
